A study of Mus musculus with 77 samples.

How the data were processed

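Of the 77 samples in 28 groups, 39 are polyadenylated RNA libraries of ICR eggs and embryos in 13 groups of 3, 24 are polyadenylated RNA libraries of C57BL/6 eggs and embryos in 8 groups of 3, and 14 are early 2-cell libraries in groups of 2. Of the 14, 10 are of the Stacc-seq type and 4, titled KLF17, of an assay left open; the files of all 14 have the same form and are called Stacc-seq type files here. Embryos were made by in vitro fertilization with WT sperm and RNA libraries by Smart-seq2, per the labels' protocols. Each sample was placed by its title and labels. Some labels conflict: the genotype field of replicates 2 and 3 with injected mRNA reads Klf18 and Klf19 mRNA, titles of RNA libraries labelled KO hold the word Pol2, and file names of the zygote libraries give early 2-cell. Groups follow the titles in these cases, with a check of the zygote libraries given after the report.

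The ICR files hold FPKM values as deposited, 1 per gene symbol for 55368 symbols, per the file names. The C57BL/6 RNA files and the Stacc-seq type files hold counts of fragments beside FPKM values as deposited, per the file headers; the former list 142552 Ensembl transcripts and the latter 44703 rows with 25277 symbols. A fragment can count for several overlapping transcripts there. Reads were aligned with STAR 2.5.0a and Bowtie 1.3.0, per the submitters' processing notes, which name the builds mm9 and mm10 without saying where each was used, so positions are given as the files list them. The counting tool, annotation and filters are not given in the sources used here. A set of 15 columns of the series-wide tables matches no sample title and was not analysed here.

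Transcripts of the C57BL/6 RNA files were given symbols through the exon structure of the Stacc-seq type files: 23688 symbols took the 1 transcript with the best structure score of at least 0.5 (median 0.997), so a gene stands for 1 transcript. With the ICR files 24817 symbols are shared, 73 of them by an older symbol. As a check, MII eggs of the series had Spearman's rho = 0.891 over 23574 symbols, and 0 after shuffling the symbols. No pair of ICR libraries was identical.

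The C57BL/6 RNA libraries held 16.08 to 34.89 M fragments, 8.37 to 27.9 M of them in tested genes. Pol II libraries held 83.83 and 82.34 M (WT), 164.24 and 179.42 M (KO) and 97.24 and 69.43 M (KO plus mRNA). Between replicates the chi-square per degree of freedom was at least 4.46, so counts vary more than by chance of sampling in every group.

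ICR FPKM were compared with limma 3.58.1 on log2(FPKM+1) with a mean-variance trend, 1 fit over the 13 groups and 19607 genes. Counts were compared with edgeR 4.0.16, by quasi-likelihood with TMM scaling, in separate fits of the C57BL/6 RNA (11460 genes), the Pol II (12123) and the libraries titled KLF17 (4211). Antibody against no antibody (9726 genes) was scaled by the deposited library totals, since TMM assumes that most genes do not change. The plan written before the data were examined had limma on log2 FPKM for these too; since the files hold counts, that became an alternative. Genes had to reach 1 FPKM in 3 RNA libraries or 2 Stacc-seq libraries. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of 1 or more; SE in edgeR fits is the log2 change over the square root of F. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

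The gene lists, 16 in all, were written before the data were examined: transient 2-cell genes (Dux, Zscan4 and MERVL-linked), transcription factors linked to genome activation, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, spliceosome, Pol II and general transcription, nuclear-encoded oxidative phosphorylation, oocyte and maternal-effect mRNAs, deadenylation and mRNA decay, cell cycle, p53 and stress, immediate-early mRNAs, pluripotency and early lineage, cumulus and granulosa markers, and sperm transcripts. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists are described with a camera adjusted p under 0.05 or 3 or more called members, and otherwise as a group. Genes of the activation wave were chosen on these samples, in 1 strain, and read in the other with fry, adjusted by Benjamini-Hochberg over the 28 such tests of a setting. Named genes are Klf17, then the 6 highest and 6 lowest log2 changes with a mean of 5 FPKM or more (1 in Stacc-seq libraries), libraries of both groups apart and a symbol that is not a clone name, then up to 4 called members of a list or, with none, the 2 with the highest level. For interactions and rescue these are the genes named before plus the 3 highest and 3 lowest.

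Both tools were tested on simulated data, with values redrawn at random around a common mean per gene and with the gene's spread in the real libraries. Changes were put into genes with a mean of 5 FPKM or more (1 in Stacc-seq libraries), so genes of lower level were not covered. The changed genes were 200 in each RNA comparison, 186 for Pol II KO, 176 for the KLF17 antibody and 164 for matKO. Log2 changes of 1.5, 2 and 3 were recovered in 22.7%, 50.7% and 85.1% of genes for CHX at 39 hpi (9 unchanged genes called) and in 100% at each size for late 2-cell KO (5). Zygotes gave 95.5%, 100% and 100% (0), MII eggs 98.5%, 100% and 100% (2), Pol II KO 0%, 1.6% and 41.7% (1), the KLF17 antibody 27.1%, 57.9% and 80% (4) and matKO 76.8%, 94.6% and 96.2% (3).

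Alternatives chosen before the data were examined were 75th percentile scaling, quantile normalization, pseudocount 0.1, no filter, only the 2 groups compared, a replicate block and leaving out each library. Added later were limma on log2 FPKM and DESeq2 for counts, pseudocount 1, scaling by library totals or by TMM, and the ICR fit without the libraries that stand apart (31 hpi control replicate 2 and 39 hpi CHX replicate 2). Replicate numbers are not said to mark shared animals or days, and in none of 20 comparisons did every same-numbered pair correlate above 0.1 (pair correlations from -0.151 to 0.278). The numbers are therefore not used as pairs. Random sets were 10000, drawn splits 100 and runs with a shared group simulated 20.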

Results

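Mouse eggs and early embryos were profiled in 77 samples, which the labels place in 28 groups. In the ICR strain, 39 polyadenylated RNA libraries covered MII eggs as a control group, and embryos at 13, 17, 25, 31, 33 and 39 hpi, each time as a control group and a CHX group; hpi and CHX are the labels' own abbreviations. In C57BL/6, 24 RNA libraries covered MII eggs, zygotes and late 2-cell embryos labelled WT or KO (genotype label Klf17Zp3cKO), and at the latter stages a KO group given Klf17 mRNA. These RNA libraries were made by Smart-seq2, a full-length method for very small inputs, with 3 libraries in each group. A further 14 libraries, 2 in each group, were of early 2-cell embryos. Of these 10 were of the Stacc-seq type, in which an antibody guides Tn5 transposase to chromatin: Pol II libraries of WT, KO and KO plus Klf17 mRNA embryos, and WT libraries with a KLF17 antibody or with no antibody. The other 4, titled KLF17, are of a control and a matKO group. For these 4 the labels name no antibody and give total RNA as the molecule, so the labels leave their assay open. Of their fragments 3.4% to 4.3% lay in genes, against 3.7% to 3.8% with the KLF17 antibody. In C57BL/6 RNA libraries the share was 50.8% to 82.3%, which argues against polyadenylated RNA in these 4. The C57BL/6 RNA libraries held 16.08 to 34.89 M fragments and the Pol II libraries 69.43 to 179.42 M. The KLF17 antibody libraries held 50.97 and 75.95 M, those with no antibody 36.97 and 37.63 M, and those titled KLF17 44.49 to 51.46 M. The ICR files give FPKM alone, so the fragments of those libraries are unknown. Their depth relative to 13 hpi control replicate 1 was estimated from the steps between low values, at 0.36 to 3.19. At 13 hpi it was 1 to 1.34 and at 39 hpi 0.36 to 0.8, so depth may differ between times. The ICR libraries listed 7198 to 13947 genes at 1 FPKM or more. Nothing in the labels says that replicates came from separate animals, so every p-value measures the spread between these samples, which may be technical. Errors are SD over the libraries of a group unless SE is named.

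Klf17, the zinc-finger transcription factor that the KO label names, was not lower in the RNA of libraries labelled KO. Its level was 89.8 ± 21.3 FPKM in MII eggs labelled KO against 88.4 ± 1.71 in WT, 128 ± 4.41 against 127 ± 39.6 in zygotes, and 136 ± 27.3 against 107 ± 9.47 in late 2-cell embryos (n = 3 each). In libraries labelled as given Klf17 mRNA the levels were 176 ± 95.6 FPKM in zygotes, with 1 library at 287 and the others, from 116 up, below the highest KO library at 133. In late 2-cell embryos they were 155 ± 8.39, or 145 to 161 against 119 to 168 in KO. Against KO the log2 difference was 0.45 (SE 0.22) in zygotes and 0.16 (SE 0.22) in late 2-cell embryos, neither past the edgeR threshold, so the added mRNA is not seen in the Klf17 level either. The log2 difference between KO and WT was 0.14 (SE 0.22) in eggs, 0.12 (SE 0.22) in zygotes and 0.41 (SE 0.22) in late 2-cell embryos, none past the edgeR threshold. Klf17 was read as transcript ENSMUST00000062747.5, on chromosome 4 from 117757836 to 117765648 on the minus strand in the files' own coordinates. A count over the whole transcript cannot show the loss of part of an mRNA or of its protein, so it neither backs nor excludes the genotype, and every comparison below is of libraries by their labels, for KO and for the mRNA. In the Pol II libraries Klf17 stood at 6.05 ± 0.188 FPKM in WT, 4.50 ± 1.84 in KO and 4.95 ± 0.305 in KO plus mRNA (n = 2 each). It was at 1.29 ± 0.162 with the KLF17 antibody, 0.432 ± 0.121 with no antibody, 0.755 ± 0.0255 in the control and 0.791 ± 0.234 in the matKO group titled KLF17. In ICR controls Klf17 RNA was 640 ± 116 FPKM in MII eggs, 318 ± 70.1 at 25 hpi and 493 ± 167 at 39 hpi (n = 3); ICR and C57BL/6 levels are not on a common scale.

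**Figure D1:**
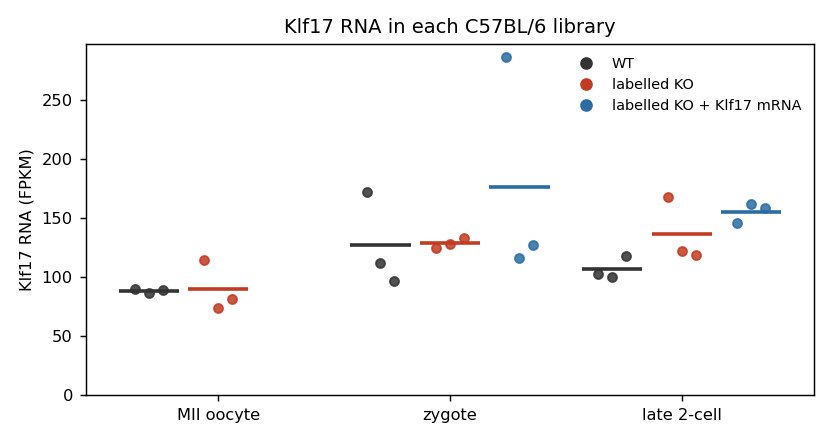
Klf17 RNA level (FPKM, linear axis from 0) in each C57BL/6 library by stage; dots are libraries and lines are group means over 3 libraries. Group means of libraries labelled KO, from 89.8 in MII eggs to 136 in late 2-cell embryos, lie at or above those of WT.

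The comparison of eggs asks which stored RNAs differ between libraries labelled KO and WT. In MII eggs labelled KO, Mt1, a metal-binding metallothionein, was higher at 83.6 ± 13.8 against 30.5 ± 1.68 FPKM in WT (n = 3; log2 change 1.58, SE 0.21, adjusted p = 0.000157). Fth1, the ferritin heavy chain, was higher at 9.27 ± 2.78 against 4.11 ± 0.277 FPKM (log2 change 1.29, SE 0.20, adjusted p = 0.0014). For both, all 3 libraries labelled KO lay above all WT libraries, and no other gene of the 11460 tested by edgeR was called. Ribosome biogenesis genes had a median log2 change of -0.22 over 47 members (camera adjusted p = 0.000124) and oxidative phosphorylation genes one of 0.20 over 45 (adjusted p = 0.00101), with 0 members called. They became adjusted p = 0.812 and 0.917 with an estimated correlation, and the other 14 lists gave adjusted p of 0.393 or more. The count rose to 4 without KO replicate 1 and to 6 without KO replicate 3. In zygotes labelled KO edgeR called 0 genes, with 488 at an unadjusted p under 0.05; limma called 0 and DESeq2 5. The sole gene under an adjusted p of 0.05 in zygotes, Marchf7, a ubiquitin ligase gene, had a log2 change of -0.95 (SE 0.17, adjusted p = 0.0271) and was singled out after its value was seen. Left out in turn, WT replicate 1 or WT replicate 3 of the zygotes gave 1 call, and the 16 gene lists gave camera adjusted p of 0.527 or more. In simulated zygote data with log2 changes of 1.5, 95.5% of the changed genes, all with a mean of 5 FPKM or more, were recovered.

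Late 2-cell embryos address how the maternal genotype relates to the main wave of genome activation. Cyb5a, cytochrome b5, was higher in libraries labelled KO, at 149 ± 16.9 against 49.9 ± 8.07 FPKM in WT (n = 3; log2 change 1.65, SE 0.15, adjusted p = 1.92e-08). Stra8, a factor of meiotic entry, was higher with a log2 change of 2.18 (SE 0.42), as were Gstm1, a glutathione transferase, with 1.60 (SE 0.39) and Insl6, an insulin-like peptide, with 1.51 (SE 0.43). Obox2 (log2 change 1.76, SE 0.33) and Pfdn4, a prefoldin subunit (1.65, SE 0.36), were higher with wide spreads, at 277 ± 265 and 159 ± 141 FPKM in KO. Among the genes that fell were Rnf11, a RING-finger protein, at 37.5 ± 6.24 against 128 ± 13.2 FPKM (log2 change -1.71, SE 0.21, adjusted p = 6.65e-06), and Pramel4 at 12.1 ± 3.46 against 50.1 ± 7.42 (log2 change -1.98, SE 0.30). Gata1, a blood-lineage factor (-1.90, SE 0.38), Msrb1, a methionine sulfoxide reductase (-1.74, SE 0.32), Frg2f1 (-1.74, SE 0.20) and H2-Q7 (-1.68, SE 0.38) were lower too, each in all 3 libraries labelled KO. In total edgeR called 477 genes, 215 higher and 262 lower, out of 11460. Without KO replicate 3 it called 299. The split moved to 296 higher and 180 lower with 75th percentile scaling, to 160 and 318 with scaling by library totals, and limma called 273, of which 63 were higher.

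Among the gene lists, transient 2-cell genes had a median log2 change of -0.69 in late 2-cell libraries labelled KO, with 3 of 40 measured above 0 (camera adjusted p = 1.27e-07, but adjusted p = 0.168 with an estimated correlation). Of the 40, 9 fell, 10 when adjusted over the list alone, and 0 rose. Members that fell included Ubtfl1, at 25.3 ± 3.51 against 63.2 ± 7.48 FPKM (n = 3; log2 change -1.25, SE 0.16), Gm8300 (-1.24, SE 0.30), B020004J07Rik (-1.29, SE 0.36) and Gm12794 (-1.57, SE 0.51). Of 28 transcription factors linked to genome activation, 5 fell and 1 rose, 6 and 1 adjusted over the list alone. Homeobox genes of the Obox family went both ways, since Obox3 fell from 72.0 ± 1.66 to 22.3 ± 4.48 FPKM (log2 change -1.62, SE 0.20) and Obox6 from 359 ± 54.0 to 148 ± 48.7 (-1.22, SE 0.22) while Obox2 rose. In WT, however, Obox2 went down from 2620 ± 343 FPKM in zygotes to 86.6 ± 6.77 in late 2-cell embryos, whereas Obox3 was at 0.587 ± 0.22 in zygotes. The higher Obox2 in KO therefore does not show its activation. Crxos, another homeobox gene, fell by 1.26 (SE 0.24). Reads are shared between copies of the Obox, Pramel and Zscan4 families, so these values are uncertain. Ribosome biogenesis genes had a median of -0.50 and 3 of 47 fell, 3 adjusted over the list alone: Mybbp1a (-1.31, SE 0.28), Noc2l (-1.15, SE 0.33) and Heatr1 (-1.04, SE 0.22). Of 62 cytosolic ribosomal proteins 1 fell, Rplp0 at 188 ± 58.9 against 412 ± 40.4 FPKM (log2 change -1.08, SE 0.17), with a list median of -0.45. Of 37 spliceosome genes 3 fell, Snrpc, Sf3b4 and Sf3a2 (-1.28, -1.18 and -1.04), and the same 3 calls held adjusted over the list alone. Polr2a, the largest Pol II subunit, fell by 1.52 (SE 0.35) and Tbpl2, the oocyte paralog of TBP, rose by 1.31 (SE 0.24), 1 each of 42 in the Pol II list. Psmb5 (-1.09, SE 0.28) was the 1 of 30 proteasome genes that fell. Camera adjusted p were 0.00209 for the transcription factors, 4.29e-10 for ribosome biogenesis, 6.72e-10 for ribosomal proteins, 0.00561 for spliceosome, 0.00532 for the Pol II list and 0.0495 for proteasome. In that order, the adjusted p with an estimated correlation were 0.02, 0.0497, 0.353, 0.336, 0.168 and 0.595. The other 9 lists gave 0.33 or more, among them cumulus and sperm markers with 0 of 5 and 0 of 8 called. Called members of those 9 lists were Ndufa5 (1.42), Krt18 (1.93), Gata3 (1.45) and the oocyte factor Figla, at 1.02 ± 0.357 against 0.0612 ± 0.0554 FPKM on 3 fragments in WT. In WT zygotes Figla was at 1.73 ± 0.697 FPKM and Gata3 at 13.7 ± 2.04, against 1.09 ± 0.387 for Gata3 in WT late 2-cell embryos. Both thus went down with time in WT, and their higher level in KO does not show activation.

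**Figure D2:**
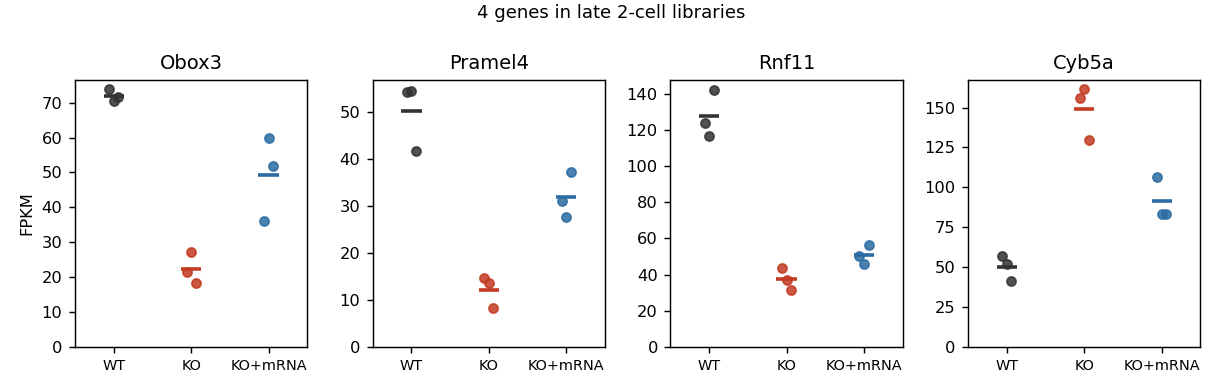
RNA level (FPKM, linear axes from 0) of Obox3, Pramel4, Rnf11 and Cyb5a in late 2-cell libraries; dots are libraries and lines are means over 3 libraries of WT, labelled KO, and labelled KO plus Klf17 mRNA. Means for Rnf11 are 128, 37.5 and 50.8, and those for Cyb5a start at 49.9 in WT and reach 149 in KO.

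Genes of the main activation wave were then taken from the ICR controls, as those called higher at 39 than at 25 hpi, which makes the set independent of the C57BL/6 libraries it was read in. Over 2194 such genes, the median log2 change in late 2-cell libraries labelled KO was -0.41, with 131 called lower and 3 higher (fry adjusted p = 0.000113). All 3 libraries labelled KO had a median below every WT library, at -0.22, -0.46 and -0.55 against -0.12 to 0.13. In MII eggs the set's median was 0.00 (fry adjusted p = 0.876) and in zygotes -0.04 (fry adjusted p = 0.562). Genes called lower at 39 than at 25 hpi showed the opposite sign, with a median of 0.32 over 1020 genes, 46 higher and 6 lower (fry adjusted p = 0.000318).

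**Figure D3:**
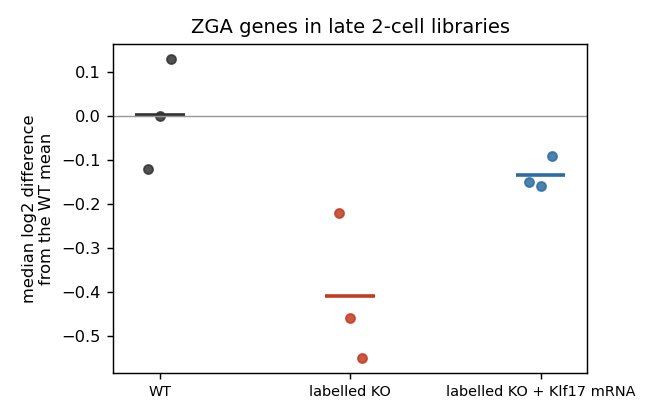
Median log2 difference from the mean of WT over 2194 genes called higher at 39 than at 25 hpi in ICR controls, for each late 2-cell library; dots are libraries. The 3 libraries labelled KO lie at -0.22, -0.46 and -0.55, and those with Klf17 mRNA at -0.15, -0.16 and -0.09.

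The groups labelled as given Klf17 mRNA, whose Klf17 level was not shown to be higher, were read for whether the differences of the KO group return towards WT. In late 2-cell embryos Pramel4 rose from 12.1 ± 3.46 FPKM in KO to 32.0 ± 4.84 with the mRNA (n = 3; log2 change 1.37, SE 0.29, adjusted p = 0.0155). Spopfm2 and the zinc-finger gene Zfp617 rose too (1.56, SE 0.31, and 1.12, SE 0.24). Pfdn4 (-1.67, SE 0.36) and Mir8092 (-1.33, SE 0.36) fell, as did Obox2, from 277 ± 265 to 102 ± 8.24 FPKM. In Pfdn4 and Obox2 1 KO library stood far above the others. Against WT, Rnf11 was still lower with the mRNA, at 50.8 ± 5.44 against 128 ± 13.2 FPKM, as was Kyat3, a kynurenine aminotransferase (-1.03, SE 0.25). Gstm1 (1.70, SE 0.39), Pstk, a tRNA kinase of selenocysteine synthesis (1.18, SE 0.26), and the chemokine-like gene Cklf (1.11, SE 0.22) were higher than in WT. Over the 2194 activation genes the median was 0.27 against KO (fry adjusted p = 0.00153; 3 higher, 0 lower) and -0.14 against WT (fry adjusted p = 0.0976; 0 higher, 6 lower). The median against WT passed with quantile normalization (-0.13, fry adjusted p = 0.0381) and without a filter (-0.18, fry adjusted p = 0.0491), so a return to the WT level is not shown. Over the 1020 genes that fell with time it was -0.26 against KO (fry adjusted p = 0.00119).

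Of the lists, 2-cell genes had a median of 0.53 with the mRNA against KO in late 2-cell embryos, ribosome biogenesis 0.33, ribosomal proteins 0.20, proteasome 0.15 and oocyte genes -0.12, with 0 members called in each and, adjusted over the list alone, 1 called higher among the 2-cell genes. Their camera adjusted p were 2.24e-06, 1.66e-05, 0.000584, 0.0356 and 0.0175, and with an estimated correlation adjusted p = 0.268, 0.268, 0.491, 0.47 and 0.412. The other 11 lists gave 0.144 or more. Against WT, transcription factors linked to activation had a median of -0.29 (camera adjusted p = 0.00782, and adjusted p = 0.0484 with an estimated correlation). Ribosome biogenesis (-0.20), ribosomal proteins (-0.25), spliceosome (-0.21) and the Pol II list (-0.11) had camera adjusted p of 0.000108, 6.36e-06, 0.00532 and 0.0164 but adjusted p = 0.275, 0.612, 0.275 and 0.275 with an estimated correlation, and the other 11 lists 0.059 or more.

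In total 67 genes were called between mRNA and KO in late 2-cell embryos, 15 higher and 52 lower, and 35 between mRNA and WT, 19 higher and 16 lower. Of the 477 genes called between KO and WT, 242 moved closer to WT than to KO, which is 50.7%. In 20 simulations of unchanged groups, the 477 genes with the lowest p gave 49.7% (46.1% to 54.3%), so the share was not above theirs. What an mRNA without effect would give for genes with a KO change was not computed, so the 50.7% shows neither a return nor its absence. Called in the opposite direction under the mRNA were 34, against 1.32 for independent lists, a figure that leaves out the shared KO libraries and so is no bound for chance. Across genes the covariance of the changes was -0.214 against -0.0687 in 20 simulations of unchanged groups that share the KO libraries, a difference of -0.145; genes are not independent replicates, and 3 shared KO libraries are too few to split. Genes higher in KO moved closer to WT in 87 of 215 cases and genes lower in KO in 155 of 262. The mRNA against KO count was 226 without KO replicate 1, 14 without KO replicate 3 and 19 without mRNA replicate 3. That against WT was 58 without WT replicate 1, 9 without WT replicate 3, 20 without mRNA replicate 2 and 17 without mRNA replicate 3. On the 2 groups alone the counts were 2 and 9. Splits of higher and lower were 32 and 29 with quantile normalization and 43 and 69 with DESeq2 against KO, and 29 and 14 with 75th percentile scaling and 65 and 26 with quantile normalization against WT. In zygotes edgeR called 0 genes between mRNA and KO (741 at an unadjusted p under 0.05; limma 0, DESeq2 2; 7 without mRNA replicate 2). Camera moved ribosome biogenesis (median -0.16, adjusted p = 1.54e-05), ribosomal proteins (0.16, 0.0434), oxidative phosphorylation (0.16, 0.0175) and oocyte genes (0.15, 0.0103) in zygotes. Those 4 gave adjusted p = 0.561, 0.968, 0.791 and 0.79 with an estimated correlation, and the other 12 lists 0.41 or more by camera.

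Whether the difference between KO and WT itself changed from zygote to late 2-cell embryo was tested as an interaction. Rnf11, at 0.248 ± 0.150 FPKM in WT and 0.356 ± 0.202 in KO zygotes (n = 3), changed its KO effect by -2.34 (SE 0.50, adjusted p = 0.0225). Cyb5a, at 71.4 ± 1.85 in WT and 71.0 ± 8.03 FPKM in KO zygotes, changed it by 1.57 (SE 0.20, adjusted p = 0.000119). The complex I assembly factor Tmem126a changed by 1.62 (SE 0.35), Pstk by 1.57 (SE 0.38) and the mitochondrial carrier Slc25a33 by -2.02 (SE 0.37). Wdr77, listed at 0 in WT zygotes and at 0.0618 FPKM in KO zygotes, was at 20.7 ± 4.01 and 15.8 ± 4.33 FPKM later. In total 84 genes were called, 35 higher and 49 lower. Ribosomal proteins had a median difference of -0.42 with 3 of 62 lower, 5 adjusted over the list alone (camera adjusted p = 3.72e-11), and the transcription factors -0.28 with 1 of 28 lower, 3 lower and 1 higher adjusted over the list alone (0.0283). Ribosome biogenesis (-0.36; 4.94e-07), proteasome (-0.29; 0.00864), spliceosome (-0.14; 0.0279) and the Pol II list (-0.18; 0.0117) had 0 members called. None of these 6 held with an estimated correlation, with adjusted p = 0.363, 0.175, 0.175, 0.452, 0.422 and 0.252, and the other 10 lists gave 0.0709 or more. For the 2194 activation genes the median difference was -0.33 (fry adjusted p = 0.0122), with 0 higher and 26 lower. The count was 180 without late KO replicate 1, 32 without late KO replicate 3, 55 without late WT replicate 2 and 29 without late WT replicate 3. Leaving out zygote libraries gave 26 for WT replicate 2, 24 for WT replicate 3, and 26, 24 and 31 for KO replicates 1 to 3; scaling changed the split to 44 higher and 31 lower (75th percentile) or 84 and 188 (quantile).

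Pol II signal over transient 2-cell genes was read in early 2-cell embryos, with 0 members called by edgeR in either comparison. The list had a median log2 change of -0.88 in libraries labelled KO, a mean of -1.70 and 4 of 47 genes above 0 (camera adjusted p = 6.58e-10), and 1.49 with the mRNA against KO (camera adjusted p = 2.44e-17). Estimating the correlation gave adjusted p = 0.0658 and 0.0285, so the KO change of the list did not hold; adjusted over the list alone 8 were lower and 19 higher. Both comparisons share the KO libraries, which hold more zeros than those with the mRNA, as given below. Tcstv1, a 2-cell gene, was at 15.0 ± 2.40 FPKM in WT, 9.37 ± 5.55 in KO and 13.8 ± 3.05 with the mRNA (n = 2 each), while Zfp352 was at 16.3 ± 0.648, 18.9 ± 5.01 and 16.3 ± 0.187. Early lineage factors had a median of 0.49 over 22 genes (camera adjusted p = 0.0274, and adjusted p = 0.389 with an estimated correlation), although Sox15 stood at 10.1 ± 11.9 against 16.2 ± 2.82 FPKM. The other 14 lists gave 0.728 or more, and with the mRNA the other 15 gave 0.0765 or more. Of the 215 genes whose RNA was later higher in late 2-cell KO libraries, 79 passed the Pol II filter. Their median Pol II change was 0.69, against -0.36 to 0.18 for 95% of 10000 random sets matched on level. Of the 262 whose RNA was lower, 216 passed, with a median of -0.53 against -0.21 to 0.07. With no filter in either fit, the KO medians were 0.25 over 292 genes higher in RNA and -0.66 over 355 lower. Their random ranges were -0.52 to 0.00 and -0.31 to -0.05, and 38% of the 292 were below 0. With the mRNA the medians were -0.79 and 0.62, against -0.17 to 0.40 and -0.13 to 0.17 for 95% of random sets. Without a filter the former was 0.05, still below its random range of 0.59 to 1.25. Both Pol II comparisons use the same KO libraries, which by itself favours opposite signs. For the 2220 activation genes the medians were -0.22 (fry adjusted p = 0.000113) and 0.13 (fry adjusted p = 0.000201), the latter turning to -0.28 in limma on log2 FPKM. Gene by gene, edgeR called 0 of 12123 in either comparison, with 1897 and 2101 at an unadjusted p under 0.05, while DESeq2 called 1648 and 1819 and limma 91 and 215. The 2 libraries labelled KO differed from each other by a chi-square of 372.87 per degree of freedom, against 23.65 in WT and 19.0 in KO plus mRNA. Of 10404 genes with a WT mean of at least 1 FPKM, they listed 994 and 1411 at 0, against 228 and 230 in KO plus mRNA. Without KO replicate 1 the counts were 3412 and 3653, and without KO replicate 2 2715 and 2977. Simulated log2 changes of 2 in this design were recovered in 1.6% of genes, so most single-gene changes were not detectable. Scaling by library totals moved the median of all genes from -0.06 to 0.09 for KO and from 0.04 to -0.58 for the mRNA.

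Antibody libraries were set against those with no antibody to show where signal rose above background. With the Pol II antibody, the 2-cell gene Zfp352 was at 16.3 ± 0.648 against 0.213 ± 0.0644 FPKM (n = 2; log2 change 6.25, SE 0.32), and Ccna2, cyclin A, at 6.82 ± 0.635 against 0.0240 ± 0.0228 (8.12, SE 0.51). Rps29, a ribosomal protein gene, stood at 21.6 ± 3.33 and Tmed6 at 14.0 ± 2.30 FPKM, both listed at 0 with no antibody. With the KLF17 antibody the signals were lower, as for Nlrp5, a maternal-effect gene, at 2.72 ± 0.670 against 0.164 ± 0.0141 FPKM (4.05, SE 0.58), and the pluripotency factor Pou5f1, at 1.12 ± 0.132 against 0.139 ± 0.114. Signal over the Klf17 gene was higher too (1.58, SE 0.28, edgeR adjusted p = 0.00876), against a median of 1.28 over all genes in the same scaling. For Pol II 8755 genes were called higher and 18 lower of 9726, and for the KLF17 antibody 3939 higher and 1 lower, the predicted gene Gm21149, named after its value was seen. Of the lists, Pol II was higher over 45 of 46 2-cell genes and 37 of 37 cell cycle genes, the lists past camera (adjusted p = 0.00704 and 0.000495, and adjusted p = 0.325 for both with an estimated correlation). It was higher over 23 of 25 activation factors, 43 of 43 ribosome biogenesis, 57 of 58 ribosomal protein, 25 of 25 proteasome, 29 of 32 spliceosome and 32 of 32 Pol II list genes. The same held for 18 of 21 oocyte, 17 of 17 decay, 23 of 24 p53, 23 of 24 immediate-early, 16 of 17 lineage and 6 of 7 sperm genes. Over 25 of 33 oxidative phosphorylation genes Pol II was higher and over 1 lower; each count was the same adjusted over the list alone. The KLF17 antibody was higher over 15 of 46 2-cell genes, 12 of 25 activation factors, 14 of 43 ribosome biogenesis, 25 of 58 ribosomal protein, 8 of 25 proteasome, 15 of 32 spliceosome and 14 of 32 Pol II list genes. It was higher over 10 of 33 oxidative phosphorylation, 7 of 21 oocyte, 9 of 17 decay, 20 of 37 cell cycle, 14 of 24 p53, 8 of 24 immediate-early and 10 of 17 lineage genes. Adjusted over the list alone these were 12, 12, 14, 26, 6, 16, 16, 7, 7, 10, 23, 15, 8 and 10, and 0 of 15 lists passed camera (0.621 or more for these 14, 0.913 for sperm genes). These counts rest on scaling by library totals, under which the median of all genes was 3.17 for Pol II and 1.28 for KLF17. With TMM the medians were 0.10 and 0.13 and the calls 1003 higher and 757 lower for Pol II and 0 for KLF17 (1696 at an unadjusted p under 0.05), so for KLF17 the calls depend on how a library-wide difference is removed. List medians changed sign likewise: for KLF17, ribosome biogenesis went from 0.93 to -0.21, 2-cell genes from 1.13 to -0.02 and immediate-early genes from 1.11 to -0.04 with TMM, and for Pol II sperm genes from 2.75 to -0.32. Quantile normalization turned further KLF17 medians, of activation factors (-0.21), spliceosome (-0.08), the Pol II list (-0.19), oocyte (-0.04), decay (-0.20), cell cycle (-0.23) and lineage genes (-0.05), and the Pol II median of lineage genes (-0.09). The 75th percentile gave 996 and 767, and 0 (1705). Quantile normalization gave 545 and 429, and 98 and 26, and DESeq2 1674 and 1378, and 734 and 323; limma called 1661 for KLF17 and the pair of groups alone gave 995. Without Pol II WT replicate 1 or 2 the count was 3165 or 3169, and without KLF17 antibody replicate 1 or 2 it was 0 in edgeR (3333 and 3371 at an unadjusted p under 0.05).

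In the libraries titled KLF17, Mt1 was lower in the matKO group, at 6.51 ± 0.528 against 15.9 ± 4.38 FPKM in the control (n = 2; log2 change -1.24, SE 0.24, adjusted p = 0.0222). The 2-cell regulator Dux was at 12.2 ± 0.288 and 11.5 ± 3.76 FPKM, and Tcstv1 at 1.63 ± 0.557 and 1.56 ± 0.0946. The second gene of 4211 that edgeR called was Tbc1d21, with a log2 change of -2.53, named after its value was seen. None of 14 lists was past camera, with adjusted p of 0.465 or more. The count was 5 without matKO replicate 1, 0 without matKO replicate 2 (173 at an unadjusted p under 0.05) and 0 without control replicate 2 (238). With limma it was 0 (162), with the replicate block 0 (250) and with quantile normalization 0 (244).

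Normal development gives the background for these differences. In ICR controls, 25 hpi against MII eggs, Zscan4d, a 2-cell gene, rose from 1.23 ± 0.85 to 93.0 ± 36.2 FPKM (n = 3; log2 change 5.38, SE 0.51) and Zfp352 to 154 ± 48.6 (6.57, SE 0.91). Mos, the kinase of meiotic arrest, fell from 1290 ± 85.5 to 2.86 ± 1.98 FPKM (-8.57, SE 0.66), as did the checkpoint gene Bub1b (-5.88, SE 0.46) and the protease gene Plat (-5.48, SE 0.48). From 25 to 39 hpi the ribosomal protein gene Rpl38 rose from 12.1 ± 4.82 to 169 ± 32.7 FPKM (3.74, SE 0.50), while the oocyte genes Rfpl4 (-3.49, SE 0.36) and Bcl2l10 (-2.72, SE 0.33) fell. Limma called 2113 genes higher and 1170 lower in the first step and 3003 and 1453 in the second, of 19607. In the first step 41 of 47 2-cell genes rose and 1 fell (camera adjusted p = 6.04e-26, but adjusted p = 0.118 with an estimated correlation), and 31 of 62 ribosomal proteins rose and 2 fell (3.42e-06). Also, 12 of 30 activation factors rose and 3 fell (0.033), 10 of 27 immediate-early genes rose and 2 fell (0.00322), and 10 of 27 p53 genes rose and 2 fell (0.0465). There 19 of 45 oocyte genes fell and 3 rose (5.12e-09), 16 of 48 ribosome biogenesis genes fell and 3 rose (2.69e-07), and 7 of 31 proteasome genes fell (0.000863). In that step 11 of 39 spliceosome genes fell and 7 rose (0.0465), and 8 of 43 in the Pol II list fell and 2 rose (0.0422). For the Pol II list the median was 0.13 while mean (-0.11) and test pointed down, and 75th percentile scaling gave a median of -0.18. The 9 lists after the 2-cell genes gave, with an estimated correlation, adjusted p = 0.52, 0.52, 0.52, 0.522, 0.107, 0.305, 0.52, 0.52 and 0.52 in that order. Lists with calls but not past camera were oxidative phosphorylation (4 rose, 3 fell; median 0.24, -0.05 with 75th percentile scaling), decay (3, 7; median 0.26, -0.09 with quantile normalization), cell cycle (12, 5) and lineage factors (7, 2).

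In the second step 59 of 62 ribosomal proteins (camera adjusted p = 7.89e-31, but adjusted p = 0.077 with an estimated correlation) and 39 of 48 ribosome biogenesis genes (2.7e-20) rose. So did 13 of 31 proteasome genes with 1 lower (8.36e-06), 20 of 43 Pol II list with 4 lower (0.00455), 15 of 45 oxidative phosphorylation with 2 lower (0.0219; median 0.36, -0.04 with 75th percentile scaling), 13 of 39 spliceosome with 2 lower (0.03) and 10 of 27 p53 genes (0.0369). Oocyte genes fell, 21 of 45 with 1 higher (3.37e-10), and of 47 2-cell genes 8 fell and 1 rose (0.03). The 8 lists after the ribosomal proteins became, with an estimated correlation, adjusted p = 0.0305, 0.21, 0.332, 0.332, 0.474, 0.598, 0.0355 and 0.782. Not past camera were the activation factors (10 rose, 5 fell), decay (8, 8), cell cycle (14, 5), immediate-early (3, 1; median 0.02, -0.28 with 75th percentile scaling) and lineage lists (4, 0). Adjusted over the list alone, the 2-cell genes gave 42 higher and 1 lower in the first step and 4 and 9 in the second. Ribosomal proteins gave 32 and 2, then 60 and 0, ribosome biogenesis 3 and 17, then 40 and 0, and oocyte genes 3 and 19, then 1 and 21. The median of all genes in the first step was 0.28, 0.16 with 75th percentile scaling and 0.00 with quantile normalization, and in the second 0.05 and -0.12 (75th percentile). Splits moved to 1907 and 1671 or 1610 and 1955 in the first step and 1992 and 2170 or 2414 and 2144 in the second, and the first step called 2074 without MII replicate 2.

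In C57BL/6, late 2-cell WT libraries were set against zygote WT libraries. Obox6, on 3 fragments in WT zygotes, went from 0.0362 ± 0.0351 to 359 ± 54.0 FPKM (n = 3). Rps19 rose from 1.13 ± 0.366 to 226 ± 54.1 (7.75, SE 0.29), and Nop16, listed at 0 in WT zygotes, reached 106 ± 16. H1f8, the oocyte linker histone, fell from 1410 ± 171 to 24 ± 0.486 (-5.77, SE 0.40), as did Dnmt1, the maintenance methyltransferase (-4.99, SE 0.21). In total 3988 genes rose and 3126 fell of 11460. Past camera were ribosomal proteins (58 of 62 rose; adjusted p = 2.33e-19), 2-cell genes (33 of 40 rose, 4 fell; 5.46e-12), and oocyte genes (32 of 44 fell, 3 rose; 9.51e-12). So were activation factors (15 of 28 rose, 5 fell; 0.00408), ribosome biogenesis (21 of 47 rose, 8 fell; 0.0443) and p53 genes (15 of 26 rose, 1 fell; 0.0443). Their adjusted p with an estimated correlation were 0.159, 0.0757, 0.0191, 0.0191, 0.454 and 0.077. The other lists held, as risen and fallen, proteasome 10 and 4, spliceosome 10 and 11 (median -0.10, 0.20 with quantile normalization), Pol II list 13 and 6, and oxidative phosphorylation 26 and 7. For decay these were 8 and 11, cell cycle 12 and 9, immediate-early 12 and 2, lineage 8 and 2, cumulus markers 2 and 3 and sperm transcripts 5 and 2, with the same counts adjusted over each list alone. Quantile normalization moved the split to 2493 and 3056 and the median of all genes from 0.13 to -0.13, and DESeq2 moved that median to 0.26.

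CHX is compared with control at each time to follow what the treatment changes as the genome is activated. At 13 hpi ribosomal protein genes had a median log2 change of -0.53 over 62 genes, with none called; Rpl4, named for its level, moved less, at 118 ± 3.66 against 128 ± 14.7 FPKM (n = 3; log2 change -0.11, SE 0.49). At 17 hpi the oocyte gene Dppa3 was at 4550 ± 859 against 4960 ± 1190 FPKM. Limma called 0 genes at both times, with 259 and 504 at an unadjusted p under 0.05; no count-based tool runs on FPKM, and leaving out 1 library gave up to 2 calls. At 13 hpi camera moved 7 lists, ribosomal proteins (adjusted p = 1.32e-15), ribosome biogenesis (-0.16; 0.0134), 2-cell genes (-0.19; 0.0186), spliceosome (-0.19; 0.0267), the Pol II list (-0.18; 0.0175), p53 genes (-0.26; 0.0175) and oocyte genes (0.15; 0.0186), none with a called member. All gave adjusted p = 0.569 with an estimated correlation, except 0.873 for 2-cell genes; the other 9 lists gave 0.119 or more, and at 17 hpi all 16 gave 0.0609 or more.

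At 25 hpi Usp38, a deubiquitinase, was lower under CHX at 6.57 ± 0.899 against 44.6 ± 9.15 FPKM (n = 3; log2 change -2.58, SE 0.38, adjusted p = 0.0026). Tiam1, an activator of Rac (-1.92, SE 0.35), Eif5, a translation initiation factor (-1.92, SE 0.30), and the predicted gene Gm6803 (-4.01, named after its value was seen) made up the 4 calls of limma. Without CHX replicate 3 there were 7, and without the libraries that stand apart at 31 and 39 hpi 372. Transient 2-cell genes had a median of -1.47 over 47 genes, with Gm4850 at 23.8 ± 18.0 against 242 ± 154 FPKM, and 22 fell when adjusted over the list alone although 0 did over all genes (camera adjusted p = 2e-17). Ribosomal proteins (-0.80; 2.03e-11; 13 lower alone), activation factors (-0.65; 0.000367; 7 lower alone), immediate-early genes (-0.74; 5.84e-05), p53 genes (-0.61; 0.00017) and lineage factors (-0.39; 0.00497; 2 lower alone) moved down, and proteasome (0.59; 5.32e-07; 1 higher alone) and oocyte genes (0.39; 7.53e-06) up. None held with an estimated correlation, giving adjusted p = 0.227 for 2-cell genes, then 0.301, 0.291, 0.291, 0.291, 0.343, 0.227 and 0.227, and the other 8 lists gave 0.195 or more.

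At 31 hpi Znhit6, a factor of snoRNP assembly, was lower under CHX at 2.52 ± 1.97 against 38.5 ± 12.2 FPKM (n = 3; log2 change -3.61, SE 0.39, adjusted p = 2.59e-06). Dimt1, an rRNA methyltransferase (-2.70, SE 0.45), the ribosomal protein genes Rps3a1 (-2.87, SE 0.55) and Rps7 (-1.85, SE 0.34) and the kinetochore gene Ndc80 (-2.42, SE 0.46) were lower, and Rln3, a relaxin (2.71, SE 0.63), was higher. Of 62 ribosomal proteins 9 fell, 26 adjusted over the list alone (camera adjusted p = 3.15e-23), of 48 ribosome biogenesis genes 2 and 7 (1.07e-07), and of 31 proteasome genes 3 and 6 (0.000219). In the same order, of 43 in the Pol II list 2 and 3 fell (0.0267), and of 45 oxidative phosphorylation genes 2 and 7 fell, with 1 higher (0.000219). With an estimated correlation the adjusted p were 0.254, 0.256, 0.383, 0.572 and 0.254; the other 11 lists gave 0.0989 or more. Limma called 35 genes higher and 76 lower. This count leaned on single libraries: it was 69, 515 and 638 without control replicates 1, 2 and 3, 47 without CHX replicate 2, and 0 on the pair of groups alone (405 at an unadjusted p under 0.05). Control replicate 2 listed 7198 genes at 1 FPKM or more, against 12655 and 13742 in its fellow controls.

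At 33 hpi the change was widest: Rpl38 was at 11.1 ± 4.09 under CHX against 80.6 ± 15.5 FPKM (n = 3; log2 change -2.79, SE 0.50, adjusted p = 0.000381), and Rps27 at 2.69 ± 0.252 against 54.7 ± 25.7 (-3.78, SE 0.55). The ribosome biogenesis genes Nop16 (-3.64, SE 0.88) and Nhp2 (-3.26, SE 0.45), the deubiquitinase Usp22 (-4.01, SE 0.50) and the pluripotency-linked factor Dppa4 (-2.59, SE 0.55) fell. Among oocyte mRNAs, H1f8 was higher at 719 ± 347 against 105 ± 31.8 FPKM (2.66, SE 0.44), as were Nobox (2.23, SE 0.39) and Bcl2l10 (2.05, SE 0.33); Hes6 (3.43, SE 0.56) and Nlrp9b (2.96, SE 0.52) were higher too. Of 62 ribosomal proteins 48 fell, 53 adjusted over the list alone (camera adjusted p = 1.11e-26), and of 48 ribosome biogenesis genes 23, 28 alone (1.46e-13). Of 45 oocyte genes 14 rose and 2 fell, the same alone (2.29e-10), 9 of 43 in the Pol II list fell, 11 alone (0.00282), and 8 of 27 p53 genes fell and 1 rose (0.0144). With an estimated correlation the adjusted p were 0.118, 0.0762, 0.0664, 0.351 and 0.571. Lists with calls but not past camera held, as risen and fallen, activation factors 3 and 10, 2-cell genes 0 and 3, proteasome 1 and 7, and spliceosome 2 and 9. Likewise oxidative phosphorylation held 2 and 7 (median -0.27, 0.00 with 75th percentile scaling), decay 2 and 4 (median -0.22, test up), cell cycle 1 and 8, immediate-early 0 and 4 and lineage 1 and 5. Limma called 929 genes higher and 1999 lower, 1133 and 1357 with 75th percentile scaling and 1350 and 1632 with quantile normalization. The count was 1690 without control replicate 1, 1621 without control replicate 2 and 1479 without CHX replicate 2.

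At 39 hpi transient 2-cell genes had a median log2 change of 0.69 under CHX, with 36 of 47 above 0 and 4 called higher (camera adjusted p = 0.00102, but adjusted p = 0.482 with an estimated correlation). Without the libraries that stand apart, among them CHX replicate 2 of this time, the median was 1.18. Zscan4d was higher, at 87.3 ± 50.4 against 26.9 ± 12.4 FPKM (n = 3; log2 change 1.52, SE 0.51, adjusted p = 0.0499; 2 of 3 CHX libraries above all controls). Zscan4e was at 6.29 ± 4.30 against 0.584 ± 0.613 (2.03, SE 0.56). The oocyte genes Nlrp4f, at 564 ± 301 against 127 ± 45.0 FPKM (2.08, SE 0.32), and Uchl1 (1.60, SE 0.26) were higher, as were the histone gene H3c7 (3.61, SE 0.72) and Gpx6, a glutathione peroxidase (3.51, SE 0.57). Lower were Rpl22 (-1.85, SE 0.38), the nucleolar helicase gene Ddx21 (-2.28, SE 0.38), Tead4, a trophectoderm factor, at 0.700 ± 0.246 against 5.30 ± 0.647 FPKM (-1.89, SE 0.35), and the cyclin gene Ccna2 (-1.55, SE 0.37). As risen and fallen over all genes and then adjusted over the list alone, 2-cell genes held 4 and 0, then 6 and 0, of 47, and oocyte genes 15 and 0, then 17 and 1, of 45 (camera adjusted p = 5.33e-08). Ribosome biogenesis held 0 and 14, then 0 and 24, of 48 (2.57e-11), and ribosomal proteins 0 and 20, then 0 and 29, of 62 (2.25e-15). Smaller numbers fell among proteasome (4; 0.000202), spliceosome (5; 0.0136), cell cycle (5; 0.0117), immediate-early (5; 0.00989), lineage (5; 0.0186) and p53 genes (2; 0.04), the Pol II list (4, with 1 higher; 0.0412) and activation factors (3, with 2 higher; 0.04). With an estimated correlation the lists from oocyte genes on gave adjusted p = 0.138, 0.138, 0.377, 0.377, 0.434, 0.401, 0.474, 0.474, 0.474, 0.474 and 0.474. Oxidative phosphorylation (0 and 3) and decay (1 and 3) were not past camera. Limma called 859 genes higher and 1027 lower, 704 and 559 with 75th percentile scaling, 946 in total without control replicate 1, and 0 on the pair of groups alone (2061 at an unadjusted p under 0.05).

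**Figure D4:**
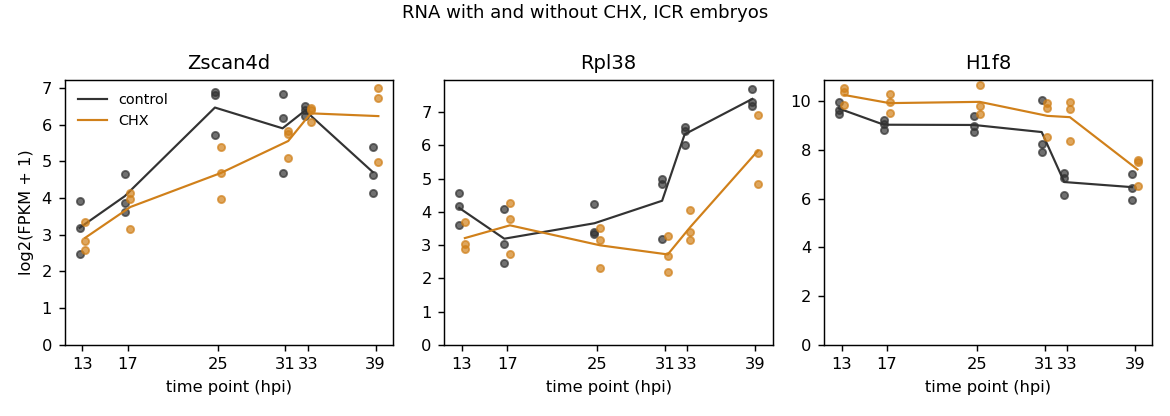
RNA level as log2(FPKM+1) of Zscan4d, Rpl38 and H1f8 in ICR control and CHX libraries at 13 to 39 hpi; dots are libraries and lines join means of 3 libraries. Zscan4d is at 26.9 FPKM in control and 87.3 under CHX at 39 hpi, and Rpl38 at 80.6 and 11.1 at 33 hpi.

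Read over the genes that rose from zygote to late 2-cell embryo in C57BL/6 WT, a set chosen outside the ICR libraries (3972 genes, 3595 measured), CHX gave medians of -0.17 at 13, 0.09 at 17, -0.34 at 25 and -0.15 at 31 hpi, with fry adjusted p = 0.527, 0.692, 0.207 and 0.597. Without the libraries that stand apart at 31 and 39 hpi they were -0.34 at 25 (fry adjusted p = 0.00566) and -0.62 at 31 hpi (fry adjusted p = 0.000153), so an effect before 33 hpi is not excluded. The median was -0.97 at 33 hpi, where 1158 fell and 8 rose (fry adjusted p = 0.000912), and -0.60 at 39 hpi, where 468 fell and 33 rose (fry adjusted p = 0.0448). The latter missed the threshold with pseudocount 0.1 (-0.82, fry adjusted p = 0.152), without a filter (-0.36, fry adjusted p = 0.0549) and over the set from limma on log2 FPKM (-0.68, fry adjusted p = 0.0522). Genes that fell between those stages (2962 measured) had medians of 0.23 at 25 (fry adjusted p = 0.0976), 0.50 at 33 (fry adjusted p = 0.000318) and 0.24 at 39 hpi (fry adjusted p = 0.035).

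The change of the CHX effect from 25 to 39 hpi was tested as an interaction. Zscan4a was at 4.35 ± 3.35 under CHX against 29.1 ± 16.4 FPKM at 25 hpi and at 15.7 ± 12.8 against 3.61 ± 3.15 at 39 hpi (n = 3; difference of log2 changes 4.07, SE 0.86, adjusted p = 0.0184). Nelfcd, a subunit of the NELF pausing complex, went the other way, from 9.34 ± 2.86 against 3.13 ± 2.47 to 1.21 ± 0.760 against 11.6 ± 7.01 FPKM (-3.86, SE 0.90). So did Noc4l, a ribosome biogenesis gene (-3.75, SE 0.83), and Brf2, a Pol III factor (-3.26, SE 0.84), while Insl6 (4.17, SE 0.93) and Zfp184 (4.11, SE 0.99) rose. In total 99 genes were called higher and 98 lower. The 2-cell list had a median difference of 2.10 with 4 of 47 higher, 18 adjusted over the list alone (camera adjusted p = 1.26e-15). Ribosome biogenesis (-1.11; 5 lower, 10 alone; 9.4e-11), and proteasome (-1.06; 1 lower, 6 alone; 1.26e-10) moved too, as did cell cycle (-0.31; 2 lower, 4 alone; 0.00857), ribosomal proteins (-0.29; 0.00367), spliceosome (-0.69; 0.00384), oxidative phosphorylation (-0.27; 0.0371; 1 lower alone) and oocyte genes (0.26; 0.0265; 8 higher alone). With an estimated correlation none held, with adjusted p = 0.289, 0.16, 0.131, 0.343, 0.749, 0.343, 0.451 and 0.548, and the other 8 lists gave 0.122 or more. The count was 120, 83 and 72 without 25 hpi control replicates 1 to 3, and 116, 71 and 64 without 25 hpi CHX replicates 1 to 3. It was 90 and 554 without 39 hpi control replicates 1 and 3, and 537 without 39 hpi CHX replicate 2.

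Genes called under CHX at 39 hpi and in late 2-cell libraries labelled KO were compared over 10628 genes measured in both series, which share no library. Called higher in both were 21 genes against 8.84 for independent lists (Fisher's exact p = 0.000309), among them Cyb5a (1.14 under CHX, 1.65 in KO), Tbpl2 (1.91 and 1.31) and Insl6 (2.42 and 1.51). Called lower in both were 27 against 15.7 (Fisher's exact p = 0.0052), among them Nelfcd (-2.38 and -1.08), Mybbp1a (-1.38 and -1.31), the developmental factor Dppa2 (-1.04 and -1.01) and Psmb5 (-1.75 and -1.09). With 75th percentile scaling 11 were lower in both (Fisher's exact p = 0.0505). Across genes the changes had Pearson's r = 0.308 and Spearman's rho = 0.375. Genes are not independent replicates, for these correlations or for Fisher's test. The overlap was not matched on expression level either, so its p-values are no firm measure of chance.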

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

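Of the tests in this part, the one on sequencing depth was chosen after seeing the data; predictions for the others were written before their results were seen. No group has 4 or more libraries, so none was tested for an outlying library.

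The CHX effect differed between 39 and 25 hpi by the interaction test for 197 genes, 99 higher and 98 lower. The widest differences were those of Insl6 (4.17), Zfp184 (4.11), Zscan4a (4.07), Brf2 (-3.26), Noc4l (-3.75) and Nelfcd (-3.86). Insl6 was at 3.63 ± 2.66 under CHX against 12.8 ± 4.33 FPKM at 25 hpi and at 16.3 ± 9.51 against 2.96 ± 3.88 at 39 hpi; Zfp184 at 39 hpi rests on a spread of 23.2 ± 35.8 FPKM. Chance is not excluded: of 100 splits drawn 5 gave as many genes, the real one included, and the highest other gave 530. Splits can keep the 39 hpi libraries grouped as labelled and mix only those of 25 hpi, so such counts need not come from chance. They do not show a structure of the samples either. Without 39 hpi CHX replicate 2, 537 genes were called.

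The difference between libraries labelled KO and WT changed from zygotes to late 2-cell embryos for 84 genes, 35 higher and 49 lower. The widest changes with enough fragments in every group were those of Tmem126a (1.62), Cyb5a (1.57), Pstk (1.57), Msrb1 (-1.99), Slc25a33 (-2.02) and Rnf11 (-2.34). Of 100 splits drawn 4 gave as many genes, the real one included. That share is under 0.05 by 1 split, and 3 others reached the count where the test foresaw none, the highest with 279. Splits can keep the late 2-cell libraries grouped as labelled and mix only the zygotes, so such counts need not come from chance. The splits therefore neither exclude chance nor show a structure of the samples. Genes near 0 in zygotes weigh on this test: Rnf11 was at 0.248 ± 0.150 FPKM in WT zygotes.

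One pattern weighed is that activation genes were lower in late 2-cell libraries labelled KO (median -0.41). A single library is argued against, since 3 of 3 KO libraries lay below every WT library. Zygotes mixed into the KO group stay open as a part of it: 142 genes at least 16-fold lower in late 2-cell than zygote WT libraries had a median of 0.90. This is under the 1 set beforehand as a bound against mixing, but not by more than its spread, since libraries ran from 0.52 to 1.25. In a plain mixture, a share of zygotes large enough for a median of -0.41 would raise these 142 genes beyond the highest library, 1.25. That argues against mixing as the whole cause. A lag within the 2-cell stage stays open too, with Spearman's rho = 0.229 over 10628 genes between the KO change and control 33 hpi minus 39 hpi (libraries 0.0859 to 0.253). The genotype named in the labels is a biological explanation that the Klf17 RNA level neither backs nor excludes. A part of mixing, a lag and the genotype therefore cannot be told apart.

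A further pattern is that Pol II libraries labelled KO list fewer genes above 0, 17104 and 14011 against 20861 and 21034 in WT. Fewer fragments are argued against, since the lowest KO library held 164 M fragments against 97.2 M for the highest other. Of 1821 genes with a WT mean of at least 1 FPKM and at 0 in either KO library, 32.1% were at 0 in both. This cannot decide on loss of Pol II from the same genes. With 994 and 1411 genes at 0 in the KO libraries, the share set beforehand for such a loss could not be reached. Low library complexity stays open: a share as low goes with it, but KO plus mRNA libraries, with 228 and 230 of the same genes at 0, gave 38%, so the share is not particular to it. The part due to the genotype stays open, as untested.

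Another pattern is that the median of transient 2-cell genes was below 0 under CHX at 25 and above 0 at 39 hpi (median difference 2.10). Without the libraries that stand apart the median difference was 2.62, from -1.47 at 25 to 1.18 at 39 hpi. Of these libraries only 39 hpi CHX replicate 2 is in the groups compared. The difference was wider without it than the reported 2.10, which argues against that library as the source. The 31 hpi library enters neither effect, so leaving it out tests nothing here. Over 12 members outside the multi-copy families the median difference was 1.05 (quartiles 0.75 to 1.68), which argues against shared reads as the whole source. A lag of CHX embryos behind controls stays open: 3 of 3 CHX libraries at 39 hpi had a higher rho with an earlier control group than with 39 hpi controls, by 0.016 to 0.034. The best of several earlier groups was taken, which by itself favours such a gap. Control replicates 1 and 3 at 31 hpi had 0.837 and 0.866 with the mean of 3 controls at 25 hpi. With each other, as single libraries, they had 0.802. A mean of 3 libraries is less noisy than 1, so these values cannot show whether such a gap occurs without CHX. What CHX does to the embryo was not tested apart from such a lag.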

How the results depend on the processing

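Limma on log2 FPKM, DESeq2, pseudocount 1, scaling by library totals, TMM for antibody libraries, and leaving out the libraries that stand apart were chosen after seeing the data. The cause was not tested for any change given here. For the libraries titled KLF17 the fit of only the 2 groups is the same as the reported one and was not run.

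With 75th percentile scaling 2 genes were called for CHX at 25 hpi (4 reported), 99 for the CHX interaction (197), 1763 for Pol II against no antibody (8773) and 0 in edgeR for the KLF17 antibody (3940; 1705 at an unadjusted p under 0.05). In that scaling 11 genes were lower both under CHX and in KO. Quantile normalization gave 319 for the CHX interaction, 1 for MII eggs (2), 91 for mRNA against WT (35), 272 for the KO interaction (84), 9 for Pol II KO (0), 104 for Pol II mRNA (0), 974 for Pol II and 124 for KLF17 against no antibody, 0 in edgeR for matKO (2; 244 at an unadjusted p under 0.05), and 57 of 150 genes higher in KO closer to WT (87 of 215), a share of 38% against 40.5%. With quantile normalization activation genes under mRNA against WT had a median of -0.13 (fry adjusted p = 0.0381), and -0.18 without a filter (fry adjusted p = 0.0491), both past the threshold where the reported -0.14 is not.

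Pseudocount 0.1 gave 1126 for CHX at 39 hpi (1886), 70 for the CHX interaction, 1 for zygotes (0), 78 for mRNA against WT, 107 for Pol II KO, 282 for Pol II mRNA, 0 in edgeR for matKO (153 unadjusted), and 235 of 395 genes lower in KO closer to WT (155 of 262), a share of 59.5% against 59.2%. Activation gene medians were then -0.82 for CHX at 39 hpi (fry adjusted p = 0.152), -0.21 for Pol II KO and, reversed, -0.28 for Pol II mRNA. Pseudocount 1 gave 56 for Pol II KO, 180 for Pol II mRNA, 395 for KLF17 and 0 in edgeR for matKO (167 unadjusted). Without a filter 1 gene was called at 17 hpi, 18 at 25 hpi, 116 for the CHX interaction, 40 for MII eggs, 12 for zygotes, 10 and 144 for mRNA against KO in zygotes and late 2-cell embryos (67), 136 for mRNA against WT, 219 for the KO interaction and 1 for matKO. Activation genes under CHX at 39 hpi had a median of -0.36 (fry adjusted p = 0.0549), and genes higher in KO RNA had a Pol II median of 0.05 under the mRNA, reversed from -0.79.

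Without the libraries that stand apart 1 gene was called at 17 hpi, 372 at 25 hpi, 808 at 31 hpi (111) and 1228 for the CHX interaction; activation genes had medians of -0.34 at 25 and -0.62 at 31 hpi, now past fry (fry adjusted p = 0.00566 and 0.000153). Only the 2 groups gave 417 at 25 hpi, 0 in limma at 31 and 39 hpi (405 and 2061 unadjusted), 14 for MII eggs, 1 for zygotes, 2 for mRNA against KO and 9 against WT in late 2-cell embryos, and 995 for KLF17. The replicate block gave 48 for the KO interaction and 0 in edgeR for matKO (250 unadjusted); numbers do not pair the libraries, with pair correlations from -0.151 to 0.278, and the block moved no other count of calls past 1.5 times.

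Limma on log2 FPKM gave 1 for MII eggs, 273 for late 2-cell KO (477), 35 for mRNA against KO, 63 against WT, 213 for the KO interaction, 91 and 215 for Pol II KO and mRNA, 1661 for KLF17, 0 for matKO (162 unadjusted), activation medians of -0.68 (CHX at 39 hpi, fry adjusted p = 0.0522), -0.16 (Pol II KO) and, reversed, -0.28 (Pol II mRNA), and 129 of 273 genes closer to WT (242 of 477), 18 of 63 among those higher in KO. DESeq2 gave 8 for MII eggs, 5 and 2 for zygote KO and mRNA, 112 for mRNA against KO, 93 against WT, 168 for the KO interaction, 1648 and 1819 for Pol II KO and mRNA, 3052 for Pol II and 1057 for KLF17 against no antibody. Library totals gave 4 for MII eggs, 1 for zygotes, 40 for the KO interaction and 1 for matKO; TMM gave 1760 for Pol II and 0 in edgeR for KLF17 (1696 unadjusted). Gene list tests past 0.05 were 104 of 348 by camera, 8 with an estimated correlation, 113 by fry and 102 with the block.

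Leaving out each library gave 0 to 2 calls at 13 and at 17 hpi in limma, 4 to 7 at 25, 47 to 638 at 31, 1479 to 3193 at 33 and 946 to 2368 at 39 hpi, 2074 to 2909 for 25 hpi against MII, 3539 to 4685 for 39 against 25 hpi and 64 to 554 for the CHX interaction. In edgeR the ranges were 2 to 6 for MII eggs, 0 to 1 for zygotes, 299 to 691 for late 2-cell KO, 0 to 7 and 14 to 226 for mRNA against KO in zygotes and late 2-cell embryos, 9 to 58 against WT, 24 to 180 for the KO interaction and 6924 to 7016 for late 2-cell against zygote WT. They were 0 to 3412 for Pol II KO, 0 to 3653 for Pol II mRNA, 3165 to 8969 for Pol II and 0 to 5563 for KLF17 against no antibody, and 0 to 5 for matKO; a lone library is assumed to vary like the other groups.

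Some named genes changed sign. In the KO interaction B020004J07Rik and Crxos came to -1.19 and -1.17 with quantile normalization and to -1.19 and -1.20 in limma. Ldhc and Oaz3, in Pol II against no antibody, came to -0.22 and -0.26 with quantile normalization, -0.18 and -0.33 with the 75th percentile, -0.22 and -0.36 in DESeq2 and -0.18 and -0.32 with TMM. Under KLF17 quantile normalization gave Spz1 -0.00, Snrpd1 -0.03, Sf3b1 -0.23 and Uqcrb -0.20. Leaving out Pol II KO replicate 2 or 1, Rrp9 ranged from -1.24 to 0.81 in Pol II KO, and under the mRNA Rrp9 from 1.04 to -1.0 and Lsm4 from 1.01 to -0.72. Of 1250 values for named genes, 1112 kept direction and side of the threshold with the 75th percentile, 1092 with quantile normalization, 1175 with pseudocount 0.1, 1183 without a filter and 1220 with the block.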

Other observations

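The checks of library stage in this part were chosen after seeing the data; the other splits of the libraries were planned.

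Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, so each is given with its real count and the highest of the others. For CHX these were 0 and 1 at 13 hpi and at 17 hpi, with 10 of 10 splits at or above the real count by limma (259 and 504 at an unadjusted p under 0.05). At 25 hpi they were 4 and 4 (2 splits as high), at 31 hpi 111 and 643 (5 splits), at 33 hpi 2928 and 154 (1 split) and at 39 hpi 1886 and 823 (1 split). The 643 genes of another split at 31 hpi point to a structure of the samples. Control 25 hpi against MII gave 3283 and 2, and control 39 against 25 hpi 4456 and 25 (1 split each). In C57BL/6 they were 2 and 0 for MII eggs, 477 and 15 for late 2-cell KO, 67 and 25 for mRNA against KO, 35 and 5 for mRNA against WT, and 7114 and 0 for late 2-cell against zygote WT, with 1 split each as high. In zygotes edgeR gave 0 and 0 for KO and 0 and 20 for the mRNA, with 10 splits as high (488 and 741 at an unadjusted p under 0.05; DESeq2 5 and 2, limma 0 and 0).

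Control replicate 2 at 31 hpi stood apart. It listed 7198 genes at 1 FPKM or more against 12655 and 13742, but 25863 above 0, the most of the 39 ICR libraries. Its depth, estimated from the steps between low values, was 3.19 times that of 13 hpi control replicate 1, so few fragments are argued against. Its Spearman's rho was 0.866 with 13 hpi controls and 0.679 with the mean of its fellows. The fellows had 0.789 and 0.770 with 13 hpi controls and 0.802 with each other. Without it and 39 hpi CHX replicate 2, 808 genes were called at 31 hpi in place of 111. An embryo group earlier than its label or a library poor in another way could each give this, and no test separated them.

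Zygote libraries, whose file names give early 2-cell, showed no shift between groups over 315 genes higher at 25 than 17 hpi in ICR controls, with medians of 0.01 (KO against WT) and 0.06 (mRNA against KO). The same genes had a median of 5.68 in late 2-cell against zygote WT libraries.

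Obox2 in late 2-cell libraries labelled KO was at 122, 126 and 583 FPKM, so 1 library drives its mean. Mt1 was higher in MII eggs labelled KO (1.58) and lower in the matKO group titled KLF17 (-1.24), in assays that are not comparable, and the difference was not tested.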
